A study of Mus musculus with 41 samples.

How the data were processed

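RNA was measured by QuantSeq 3′ mRNA sequencing, which reads 1 tag near the 3′ end of each polyadenylated transcript, in 41 libraries of E14 mouse embryonic stem cells. Per the submitters' processing notes, reads were aligned to GRCm38 with STAR 2.7.6a and assigned to genes with featureCounts 2.0.1 of the Subread package. The deposited table holds reads scaled to a common library size (CPM) for 55487 Ensembl genes, of which 55141 carry a gene symbol and 346 carry only an identifier. Each of its columns sums to 1000000 CPM, all 41 columns were used, and no length scaling or log transformation is present in the values. Because the smallest step in a column equals 1 read, the reads behind each value were recovered, and 100% of 766190 values above 0 were whole within a tolerance of 0.01 reads. Depth was therefore 3424064 to 5736053 assigned reads per library, with a median of 4581394. A count of 0 allows up to 3 reads, which is 0.523 to 0.876 CPM depending on the library, and such limits cover counting error only.

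Libraries were grouped by line and medium as the labels give them, into 12 groups. Gene positions are those of the GRCm38 annotation. Values were analysed as log2(CPM + 1) for 16967 genes with at least 1 CPM in at least 3 libraries. Groups were compared with limma 3.58.1 in R 4.3.3, as 1 mean per group over all 41 libraries (29 residual degrees of freedom) with empirical Bayes moderation, a mean-dependent trend and robust variances. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 1.5-fold (0.58 on the log2 scale), and, where both Esrrb-depleted lines were averaged, only if both lines changed in the same direction. Log2 changes are given with the standard error of the fit. The 17 comparisons were both depleted lines against WT at each of 4 times, each AloXR time against 2iL in WT and in the depleted lines, the difference between these changes, and KO3 against KO2 at each time. Esrrb was also compared by exact two-sided permutation tests on log2(CPM + 1). All comparisons, lists and alternatives were chosen before the data were examined, except where stated. The limma p-values measure the spread between libraries within each line and time, for 1 WT line and 2 depleted lines. The spread between lines of the same genotype does not enter them. They therefore cannot tell an effect of Esrrb loss from other differences between the lines. The labels do not say whether libraries of a group are separate cultures or technical repeats.

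In all, 30 fixed gene lists were tested: naive pluripotency, core pluripotency, formative, primed epiblast, mesendoderm, trophoblast, primitive endoderm, neuroectoderm, primordial germ cell, two-cell-like, methylation-sensitive germline, ERK response, Wnt response, Nodal and activin response, retinoic acid response, LIF and STAT3 response, epithelial, mesenchymal, fibroblast and feeder, haematopoietic, oxidative phosphorylation, glycolysis and hypoxia, p53 response, unfolded protein response and amino acid stress, cholesterol biosynthesis, cell cycle (G2 and M), ribosomal protein, mitochondrially encoded, immediate early and heat shock stress, and imprinted. Each was tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Some genes stand in more than 1 list, for example 10 of 26 measured naive pluripotency genes and 7 of 24 measured trophoblast genes.

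Genes named in the text follow a fixed rule: Esrrb and its relative Esrra in every comparison, up to 4 called members per list with the largest change, the 10 largest rises and 10 largest falls of each comparison with WT and of each course (5 and 5 for the differences of changes and for KO3 against KO2) among genes with a group mean of at least 5 CPM, and 17 reference genes. Esrrg did not pass the filter. Any gene named outside the rule was chosen after its values were seen and is marked so. The number of libraries in the direction of a change was counted against the mean of the control libraries.

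Segments of neighbouring genes shifted together in a depleted line were searched among 8477 genes with at least 10 CPM, as runs of at least 15 genes with a median shift of at least 0.2 (log2) and a score above the highest of 20 shuffles of gene order, with 95% intervals from 1000 bootstraps over genes. The test was tested on simulated data made from the library depths with a dispersion of 0.02 and 200 changed genes. For both depleted lines against WT in 2iL it recovered 22 of 67 genes changed 1.5-fold, 62 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 4 of the unchanged genes called. At AloXR day 3 it recovered 19 of 67, 64 of 67 and 66 of 66, with 12 unchanged genes called. The simulated libraries varied independently with the same dispersion for all genes, unlike the real 2iL libraries described below. These counts therefore do not give error rates for the real data.

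Alternatives were other pseudocounts (0.25 and 5 CPM), other filters, other fold minimums, median-of-ratios scaling, quantile normalization, edgeR 4.0.16 quasi-likelihood tests on the recovered reads, a fit to only the groups compared, each library left out in turn, each depleted line alone, and fry for the lists. Added after the data were seen were a fit with the running median of 41 neighbouring genes subtracted in each depleted line (called position-centred), a fit without the third 2iL library of each line, and a fit with the order number of the libraries as a block. Reads were not realigned, exon-level coverage of Esrrb was not analysed here, and genotypes were taken from the labels. Tables and plots were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and the data.table package of R, version 1.17.8.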

Results

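Transcript levels were measured in E14 mouse embryonic stem cells that carried Esrrb (WT) and in 2 lines genetically depleted for Esrrb (KO2 and KO3). Esrrb is an orphan nuclear receptor of the naive pluripotency network. Cells were sampled in 2iL medium, which holds cells in naive pluripotency with inhibitors of MEK and GSK3 plus LIF. They were also sampled on the way to formative pluripotency, after 1 day in N2B27 followed by 1, 3 or 5 days in AloXR medium. AloXR holds activin A, the tankyrase inhibitor XAV and the retinoic acid receptor inverse agonist BMS. Of the 41 libraries, 15 were WT, 15 KO2 and 11 KO3. Groups held 3 libraries in 2iL and 4 in AloXR, except KO3 at day 3 and day 5 with 2 libraries each. Libraries held 3424064 to 5736053 assigned reads and showed at least 1 read for 17460 to 20161 genes. Replicate libraries of a group correlated across genes with Pearson's r between 0.981 and 0.995 (genes are not independent replicates). Mitochondrially encoded transcripts took 3.19% ± 0.92 of reads in WT, 4.11% ± 1.09 in KO2 and 3.59% ± 1.12 in KO3 in 2iL (SD, n = 3 each). At day 5 the shares were 2.34% ± 0.17 in WT (n = 4), 2.83% ± 0.13 in KO2 (n = 4) and 3.37% ± 0.09 in KO3 (n = 2).

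Esrrb (ENSMUSG00000021255, chromosome 12, 86361117 to 86521628, GRCm38) was lower but not absent in both depleted lines in 2iL. The labels do not give the deleted part of the gene, so its tags do not measure functional protein. In 2iL the WT libraries held 434.35, 380.79 and 308.95 CPM of Esrrb, the KO2 libraries 51.99, 55.19 and 56.7 CPM, and the KO3 libraries 102.77, 135.62 and 165.62 CPM. At day 1, Esrrb stood at 17.33, 13.09, 17.75 and 12.15 CPM in WT, at 5.52, 4.83, 1.86 and 1.64 CPM in KO2, and at 41.35, 38.49, 26.14 and 29.36 CPM in KO3, so that KO3 lay above WT. At day 3, WT held 1.83, 1.75, 1.19 and 1.63 CPM of Esrrb, KO2 3.2, 1.26, 2.29 and 1.16 CPM, and KO3 6.17 and 4.87 CPM. At day 5, Esrrb was near the detection limit in WT (0.87, 0.99, 0 and 0.65 CPM), KO2 (0.46, 0.24, 0 and 0.89 CPM) and KO3 (1.69 and 0 CPM), where 0 allows up to 3 reads. The difference of both depleted lines from WT was -2.11 (log2) in 2iL, with an exact two-sided permutation p of 0.0119, the smallest that 84 splits allow. These values average single libraries, whereas limma below averages the 2 lines with equal weight. The difference over single libraries was -0.42 at day 1 (exact p = 0.632), 0.54 at day 3 (exact p = 0.186) and -0.12 at day 5 (exact p = 0.757). By limma, Esrrb was called lower in 2iL (-2.11 ± 0.27, adjusted p = 4.73e-08, 6 of 6 libraries) and higher at day 3 (0.74 ± 0.25, adjusted p = 0.0265, 4 of 6 libraries), the latter at 5 to 9 reads per WT library and not by edgeR or in KO2 alone. Its relative Esrra stood at 0.11 ± 0.20 in 2iL (adjusted p = 0.765) and fell at day 3 (-0.73 ± 0.18, adjusted p = 0.00206), a call not kept in KO3 alone.

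**Figure D1:**
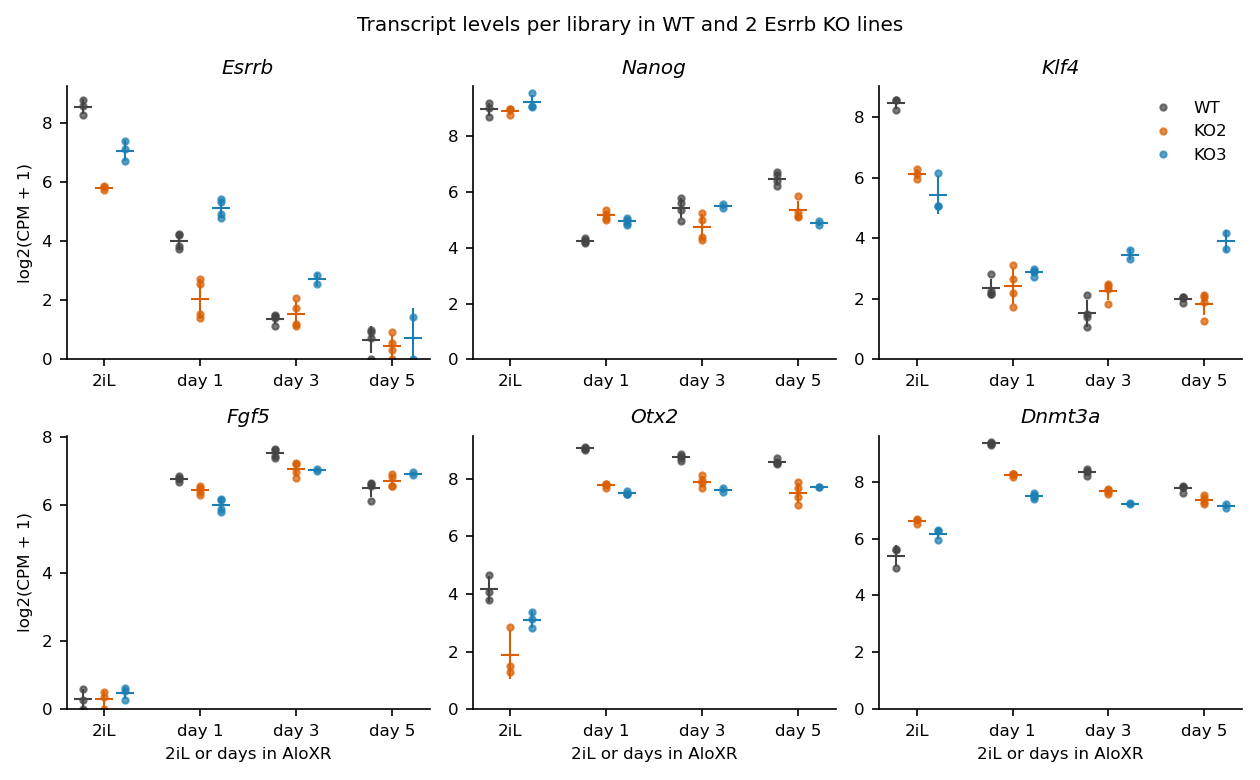
Levels of 6 transcripts per library as log2(CPM + 1) in 2iL and after 1, 3 and 5 days in AloXR, for WT, KO2 and KO3 (points, libraries; horizontal bars, group means; vertical bars, SD). Esrrb was 374.69 CPM on average in WT in 2iL and 0.63 CPM at day 5, Klf4 was lower in both depleted lines in 2iL, and Otx2 was lower in both at every time.

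In 2iL, the comparison of both depleted lines with WT asks what Esrrb loss does to naive cells. Transcripts of naive regulators fell. Klf4, a Krüppel-like factor of the naive network, was 352 CPM in WT, 69.0 in KO2 and 45.2 in KO3 (-2.68 ± 0.24, adjusted p = 6.44e-12). Nr0b1, an orphan nuclear receptor that binds Esrrb, fell by 3.37 on the log2 scale. Nanog stood at 506 CPM in WT, 483 in KO2 and 608 in KO3 and was not called (0.10 ± 0.17, adjusted p = 0.734). Among all genes with at least 5 CPM, the imprinted growth regulator RNA H19 (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143) rose most, from 2.35 CPM in WT to 243 in KO2 and 96.9 in KO3 (5.44 ± 0.45, adjusted p = 9.65e-11). Lefty1, a secreted Nodal inhibitor, rose by 4.40 ± 0.40 (adjusted p = 6.09e-10), and the keratin gene Krt19 by 3.62 ± 0.22 (adjusted p = 1.76e-17). The deepest falls were those of the uridine phosphorylase gene Upp1 (-4.54 ± 0.28), the membrane proteolipid gene Mal (-4.53 ± 0.24), the adenylate kinase gene Ak4 (-4.35 ± 0.22) and Dnajc6 (-4.15 ± 0.28). Each of these called genes lay beyond all 3 WT libraries in 6 of 6 depleted libraries. Limma called 2666 genes, 1376 higher and 1290 lower (1266 and 1364 under quantile normalization, 1159 and 1302 in edgeR).

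Of 26 measured naive pluripotency genes, 10 fell, 2 rose and 14 were not called (the same counts when adjusted over the list alone, camera adjusted p = 5.48e-05). Nr0b1, Jam2 (-3.25 ± 0.24), Tcl1 (-3.10 ± 0.26) and Klf4 fell most. Tfcp2l1, a further naive transcription factor, fell from 618 CPM in WT to 283 in both lines (-1.12 ± 0.21, adjusted p = 6.76e-05). LIF and STAT3 response genes fell too, 6 of 14 (6 adjusted over the list alone, camera adjusted p = 6.45e-04). Among them were the STAT3 feedback gene Socs3 (-1.57 ± 0.30) and the LIF co-receptor gene Il6st (-0.92 ± 0.19). Zfp42, a marker of naive cells, fell by 0.73 (adjusted p = 0.0422, 5 of 6 libraries), a call that ended in edgeR, in KO3 alone and in 6 of 9 fits that left out 1 library. Of 13 core pluripotency genes, Sox2 (-1.44 ± 0.24) and Utf1 fell, 2 in all (2 adjusted over the list alone, camera adjusted p = 0.319). Pou5f1, whose reads can be shared with near-identical pseudogenes, stood at 13.8, 14.9 and 16.7 CPM in WT, KO2 and KO3.

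Two-cell-like transcripts, the gene families expressed in the early embryo, rose in the depleted lines in 2iL, 7 of 10 (7 adjusted over the list alone, camera adjusted p = 7.74e-06). Examples are Zscan4c (1.43 ± 0.24) and Usp17la, members of multicopy families whose copies can share reads. Most genes of this list were lower in KO3 than in KO2, as described below. Imprinted genes rose, 9 of 20 (9 adjusted over the list alone, camera adjusted p = 1.28e-05). Peg10, a retrotransposon-derived placental gene (ENSMUSG00000092035, chromosome 6, 4747306 to 4760517), rose from 7.85 CPM to 151 in KO2 and 156 in KO3. Peg10 lies on chromosome 6, where genes of KO3 were higher by a median of 0.32 (log2). Primed epiblast genes rose, 6 of 14 against 1 that fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.00244, adjusted p = 0.0802 with an estimated correlation). Nodal (1.67 ± 0.28) was among them. Methylation-sensitive germline genes rose in 9 of 20 cases and fell in 3 (10 and 3 adjusted over the list alone, camera adjusted p = 0.00351, adjusted p = 0.0823 with an estimated correlation). Mael, a piRNA pathway gene, was in front (2.25 ± 0.28). Mesenchymal genes rose in 6 of 21 cases and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.00918, adjusted p = 0.154 with an estimated correlation). The member that fell was Vim, the intermediate filament vimentin. Fibroblast and feeder markers, among them Mmp2 (1.71 ± 0.28), moved with them, 5 of 13 rising (6 adjusted over the list alone, camera adjusted p = 0.0289, adjusted p = 0.166 with an estimated correlation).

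Metabolic lists shifted in 2iL, some of them with counts that depended on the fit. Glycolysis and hypoxia genes fell, 5 of 24 (5 adjusted over the list alone, camera adjusted p = 0.00743, adjusted p = 0.418 with an estimated correlation and 0.788 without 2iL library 3 of each line). Hexokinase Hk1 (-1.97 ± 0.17) and the kinase gene Pdk1 (-1.32 ± 0.21) were 2 of these. Cholesterol biosynthesis genes rose, 4 of 22 (4 adjusted over the list alone, camera adjusted p = 0.00497, adjusted p = 0.47 with an estimated correlation). Of this list, 8 rose without 2iL library 3 of each line (camera adjusted p = 2.37e-04) and 3 when position-centred (camera adjusted p = 0.00246). Oxidative phosphorylation genes fell as a list with 1 of 30 called, Sdhb (1 adjusted over the list alone, camera adjusted p = 0.00125, adjusted p = 0.166 with an estimated correlation). Cell cycle genes also fell with 3 of 20 called (3 adjusted over the list alone, camera adjusted p = 5.48e-05, adjusted p = 0.376 with an estimated correlation). Without 2iL library 3 of each line 5 were called lower (camera adjusted p = 7.19e-06), and 1 when position-centred (camera adjusted p = 1.46e-04). Unfolded protein response and amino acid stress genes rose, 5 of 16 (5 adjusted over the list alone, camera adjusted p = 0.0248, adjusted p = 0.376 with an estimated correlation). The number was 7 without 2iL library 3 of each line (camera adjusted p = 0.00485) and 3 when position-centred (camera adjusted p = 0.0393). Trophoblast genes rose in 7 of 24 cases and fell in 3 (9 and 4 adjusted over the list alone). Their camera adjusted p of 0.0481 was lost with an estimated correlation (adjusted p = 0.376), when position-centred (0.0526) and without the 2iL libraries numbered 3 (0.13). These libraries stood apart in each line, with 121, 107 and 116 CPM of Dnmt3b in WT, KO2 and KO3 against 39.7 to 59.9 CPM in the other 2iL libraries.

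Lineage and signalling lists went both ways in 2iL. Mesendoderm genes rose in 3 and fell in 5 of 20 cases (3 and 5 adjusted over the list alone, camera adjusted p = 0.727, median 0.18, mean -0.07). Bmp4 (-2.90 ± 0.27) and Gsc (-2.50 ± 0.23) were lower. Neuroectoderm genes rose in 3 and fell in 4 of 16 (3 and 5 adjusted over the list alone, camera adjusted p = 0.39). The neural factors Sox21 (-2.35 ± 0.33) and Sox1 (-2.29 ± 0.35) were lower. Primordial germ cell genes rose in 3 and fell in 4 of 13 (4 and 4 adjusted over the list alone, camera adjusted p = 0.727, median 0.32, mean -0.20). Nodal and activin response genes rose in 4 and fell in 4 of 15 (4 and 5 adjusted over the list alone, camera adjusted p = 0.727, median -0.03, mean 0.31). Wnt response genes rose in 4 and fell in 3 of 17 (4 and 4 adjusted over the list alone, camera direction down with an adjusted p of 0.787, median 0.21, mean 0.05). Lef1, a Wnt effector, fell (-1.44 ± 0.17), a call not kept in KO2 alone. Retinoic acid response genes rose in 6 of 14 cases and fell in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.175). The carrier gene Crabp2 was highest (1.91 ± 0.22). With a pseudocount of 5 CPM limma called 1396 genes in this comparison, and with only the 2iL libraries in the fit 1385.

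At day 1 of AloXR, the comparison with WT asks whether depleted cells enter the formative program alike. Several of its genes were lower. Dnmt3a, a de novo DNA methyltransferase, was 653 CPM in WT, 303 in KO2 and 182 in KO3 (-1.47 ± 0.09, adjusted p = 3.94e-17), and the carbonic anhydrase gene Car14 fell (-2.20 ± 0.16, adjusted p = 3.82e-15). Otx2, a homeobox factor of formative cells (ENSMUSG00000021848, chromosome 14, 48657677 to 48673819), fell from 532 CPM to 219 and 180 (-1.42 ± 0.17, adjusted p = 1.04e-07). Fgf5, a growth factor gene of the early epiblast, was 109 CPM in WT against 85.7 and 63.7 in KO2 and KO3 and missed the fold minimum (-0.56 ± 0.12, adjusted p = 4.00e-04). Pou3f1 stood at 387, 415 and 370 CPM (0.02 ± 0.15, adjusted p = 0.947). Trophoblast-associated transcripts rose, among them Krt19 (3.47 ± 0.19), Peg10 (3.36 ± 0.23) and Tfap2c, a transcription factor of trophoblast and germ cells (2.71 ± 0.33, adjusted p = 1.20e-07). All of these called genes were beyond the 4 WT libraries in 8 of 8 depleted libraries. H19 rose by 5.14 ± 0.39 and Upp1 fell by 4.16. Limma called 2005 genes, 1071 higher and 934 lower (974 and 1075 under quantile normalization), and 848 with a pseudocount of 5 CPM.

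The formative list fell at day 1, with 11 of 27 genes lower, 1 higher and 15 not called (the same counts adjusted over the list alone, camera adjusted p = 1.68e-07). Otx2 and Sall2 (-1.99 ± 0.13) lie in a chromosome 14 segment in which most genes were lower in both depleted lines, and Otx2 missed the fold minimum when position-centred (-0.56 ± 0.17, adjusted p = 0.0216). The list then held 8 lower genes (camera adjusted p = 9.9e-07). Trophoblast genes rose, 13 of 24 (13 adjusted over the list alone, camera adjusted p = 4.96e-12). Primitive endoderm genes rose, 8 of 22 (8 adjusted over the list alone, camera adjusted p = 1.20e-08). The basement membrane collagens Col4a2 (2.21 ± 0.20) and Col4a1 (2.18 ± 0.14) rose most among the named ones. Mesenchymal genes rose in 11 of 21 cases and fell in 1 (11 and 2 adjusted over the list alone, camera adjusted p = 1.20e-08). Examples are the calcium-binding S100a6 (2.47 ± 0.24), the annexin Anxa2 (2.27 ± 0.17) and Tagln (2.19 ± 0.21), an actin-binding protein. Fibroblast and feeder markers moved with them, 6 of 13 rising and 1 falling (6 and 1 adjusted over the list alone, camera adjusted p = 0.0305, adjusted p = 0.138 with an estimated correlation). Epithelial genes rose, 4 of 18 (4 adjusted over the list alone, camera adjusted p = 0.00407, adjusted p = 0.207 with an estimated correlation), Krt8 among them (2.28 ± 0.16). P53 response genes rose, 3 of 18 (3 adjusted over the list alone, camera adjusted p = 0.00155, adjusted p = 0.208 with an estimated correlation), namely Perp (2.49 ± 0.15), Cdkn1a (1.31 ± 0.19) and Mdm2 (0.90 ± 0.10). Mitochondrially encoded genes rose as a list with 1 of 9 called, mt-Nd6 (1 adjusted over the list alone, camera adjusted p = 0.0213, adjusted p = 0.302 with an estimated correlation). The share of mitochondrial reads was 3.10% in WT, 3.81% in KO2 and 4.30% in KO3 at that time. Imprinted genes again rose, 10 of 20 (11 adjusted over the list alone, camera adjusted p = 9.49e-09), as did two-cell-like genes, 7 of 10 (7 adjusted over the list alone, camera adjusted p = 4.30e-06). The naive list held 4 higher and 4 lower genes of 26 (4 and 4 adjusted over the list alone, camera adjusted p = 0.848, median 0.02, mean -0.04). Nr0b1 fell within it (-2.39 ± 0.26), and Nanog rose from 18.1 CPM in WT to 35.0 in KO2 and 29.9 in KO3 (0.80 ± 0.15, adjusted p = 5.47e-05).

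At day 3, naive transcripts that WT had lost were higher in the depleted lines. Klf5, a Krüppel-like factor, was 18.1 CPM in WT, 69.9 in KO2 and 148 in KO3 (2.41 ± 0.14, adjusted p = 1.26e-17). Fbxo15 rose by 2.65 ± 0.25 (adjusted p = 5.91e-10), Dppa2 by 2.28 ± 0.28 (adjusted p = 3.03e-08) and Zfp42 by 1.75 ± 0.25 (adjusted p = 3.88e-07). Each of these lay above all 4 WT libraries in 6 of 6 depleted libraries. Klf4 rose by 1.35 ± 0.23 (6 of 6 libraries, 5 above all WT) and Tfcp2l1 by 1.13 ± 0.20 (6 of 6, 3 above all WT), both at levels of 3.87 to 10.1 CPM, far below those of 2iL. Among the strongest rises were H19 (5.38 ± 0.42), the reproductive homeobox genes Rhox6 (5.00 ± 0.45) and Rhox9 (4.24 ± 0.37), which are multicopy genes, Peg10 (4.87 ± 0.25) and the small heat shock protein gene Cryab (4.50 ± 0.29). Ndrg2, in the chromosome 14 segment, fell most (-2.96 ± 0.26), followed by the cadherin Cdh22 (-2.57 ± 0.25) and Sycp3, a synaptonemal complex gene (-2.51 ± 0.27). Nanog stood at 43.1 CPM in WT, 26.7 in KO2 and 44.5 in KO3 (-0.31 ± 0.16, adjusted p = 0.152). Limma called 2931 genes, 1830 higher and 1101 lower (1418 and 1381 under quantile normalization), and 1338 with a pseudocount of 5 CPM.

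Of the naive list, 16 of 26 genes rose at day 3 and 10 were not called (17 rose adjusted over the list alone, camera adjusted p = 5.89e-10). Trophoblast genes rose in 19 of 24 cases (20 adjusted over the list alone, camera adjusted p = 1.13e-18). Tfap2c was 0.9977 CPM in WT, 18.5 in KO2 and 45.5 in KO3 (3.86 ± 0.35, adjusted p = 2.61e-10). Cdx2, a trophoblast master regulator, was listed at 0 CPM in all 4 WT libraries and stood at 0.28 CPM in KO2 and 1.31 CPM in KO3, a rise called by limma in both lines together (adjusted p = 0.0171, 4 of 6 libraries) and not in KO2 alone. ERK response genes rose, 12 of 18 (13 adjusted over the list alone, camera adjusted p = 6.08e-07). They include Phlda1 (2.92 ± 0.34) and the ERK phosphatases Dusp5 (2.51 ± 0.17) and Dusp4 (1.90 ± 0.46). Immediate early and heat shock stress genes rose with them, 7 of 15 (8 adjusted over the list alone, camera adjusted p = 6.79e-05), among them Hspb1 (2.82 ± 0.19) and Junb (2.04 ± 0.23). Primordial germ cell genes rose, 6 of 13 (6 adjusted over the list alone, camera adjusted p = 1.08e-05). The germ cell genes Prdm1 (1.81 ± 0.19) and Dazl (1.60 ± 0.24) are 2 of them. Methylation-sensitive germline genes rose in 11 of 20 cases and fell in 2 (11 and 2 adjusted over the list alone, camera adjusted p = 1.10e-05), with Taf7l at 2.80 ± 0.33. Primitive endoderm genes rose, 12 of 22 (13 up and 1 down adjusted over the list alone, camera adjusted p = 1.71e-08). Dab2 rose by 2.17 ± 0.36, whereas Gata6 (1.60 ± 0.32) and Lama1 (2.22 ± 0.28) were higher in KO3 and not called in KO2 alone. Formative genes split into 5 higher and 7 lower of 27 (5 and 9 adjusted over the list alone, camera adjusted p = 0.0716). The methyltransferase cofactor Dnmt3l was up (3.72 ± 0.33) and Car14 down (-2.32 ± 0.17). Glycolysis and hypoxia genes fell in 10 of 24 cases and rose in 1, Ndrg1 (10 and 1 adjusted over the list alone, camera adjusted p = 2.40e-04, adjusted p = 0.213 with an estimated correlation). Ribosomal protein genes shifted down by a median of 0.20 on the log2 scale with 1 of 32 called, Rpl15 (1 adjusted over the list alone, camera adjusted p = 8.31e-07, adjusted p = 0.235 with an estimated correlation).

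At day 5, genes of ERK signalling were higher in the depleted lines. Dusp6, an ERK phosphatase, was 77.0 CPM in WT, 436 in KO2 and 448 in KO3 (2.58 ± 0.20, adjusted p = 1.76e-11). The ERK inhibitor gene Spry4 rose by 2.98 ± 0.26 (adjusted p = 4.23e-12) and the ETS factor Etv4 by 2.19 ± 0.20 (adjusted p = 1.92e-11). Lef1 rose from 14.5 CPM to 41.4 and 66.9 (1.79 ± 0.16, adjusted p = 1.11e-11) and Pou3f1 from 168 CPM to 435 and 519 (1.47 ± 0.16, adjusted p = 8.24e-09). Nanog fell from 89.6 CPM to 40.8 and 28.8 (-1.36 ± 0.16, adjusted p = 6.61e-09). The forebrain factor Six3 fell most, from 21.4 CPM to 0.49 in KO2 and 1.77 in KO3 (-3.44 ± 0.26, adjusted p = 5.40e-14). Glucose transporter transcripts fell, Slc2a1 from 973 CPM to 339 and 241 (-1.78 ± 0.23, adjusted p = 5.33e-07) and Slc2a3 as well (-2.37 ± 0.34). All genes named in these sentences lay beyond the 4 WT libraries in 6 of 6 depleted libraries. Six3 lies in a KO2 chromosome 17 segment with a median of -0.76, and its fall exceeds that shift. Limma called 3491 genes, 1508 higher and 1983 lower, and 1731 with a pseudocount of 5 CPM. The excess of lower genes depends on scaling, with 1720 higher and 1665 lower under median-of-ratios scaling, 1615 and 1695 under quantile normalization, and 1643 and 1705 in edgeR.

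ERK response genes rose at day 5 in 11 of 18 cases (11 adjusted over the list alone, camera adjusted p = 7.24e-10). Glycolysis and hypoxia genes fell, 15 of 24 (15 adjusted over the list alone, camera adjusted p = 1.12e-09). They include the mitophagy gene Bnip3 (-2.09 ± 0.30) and Ero1l (-1.58 ± 0.17), an endoplasmic reticulum oxidase that lies in the chromosome 14 segment. Naive genes rose in 11 of 26 cases and fell in 2 (11 and 2 adjusted over the list alone, camera adjusted p = 2.39e-04). Fgf4, a growth factor gene of pluripotent cells, was 6.30 CPM in WT, 34.6 in KO2 and 28.2 in KO3 (2.17 ± 0.16), and Klf5 was up by 1.68 ± 0.14. Formative genes rose in 9 and fell in 6 of 27 cases (9 and 7 adjusted over the list alone, camera adjusted p = 0.158, or 0.0304 when position-centred). Trophoblast genes rose in 11 of 24 cases and fell in 1, Fgfr2 (11 and 1 adjusted over the list alone, camera adjusted p = 4.65e-05). Peg10 rose by 3.44 ± 0.25, and Tfap2c (1.82 ± 0.35) was not called in KO2 alone. Primitive endoderm genes rose in 10 of 22 cases and fell in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 8.80e-07). Gata6 was not called because KO2 and KO3 differed in sign. Haematopoietic markers rose, 3 of 7 (3 adjusted over the list alone, camera adjusted p = 0.0325, adjusted p = 0.102 with an estimated correlation), among them the lysosomal Laptm5 (1.37 ± 0.21). Imprinted genes rose in 11 of 20 cases and fell in 2 (11 and 2 adjusted over the list alone, camera adjusted p = 1.91e-05). H19 was at 2.09 ± 0.42 and Plagl1 at 2.20 ± 0.27. Neuroectoderm genes rose in 3 and fell in 5 of 16 (3 and 5 adjusted over the list alone, camera direction down with an adjusted p of 0.843, median 0.09, mean -0.17). Retinoic acid response genes rose in 1 and fell in 4 of 14 (1 and 4 adjusted over the list alone, camera direction down with an adjusted p of 0.598, median 0.09, mean -0.23). Lower members were the retinaldehyde reductase gene Dhrs3 (-2.15 ± 0.28) and Crabp2.

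**Figure D2:**
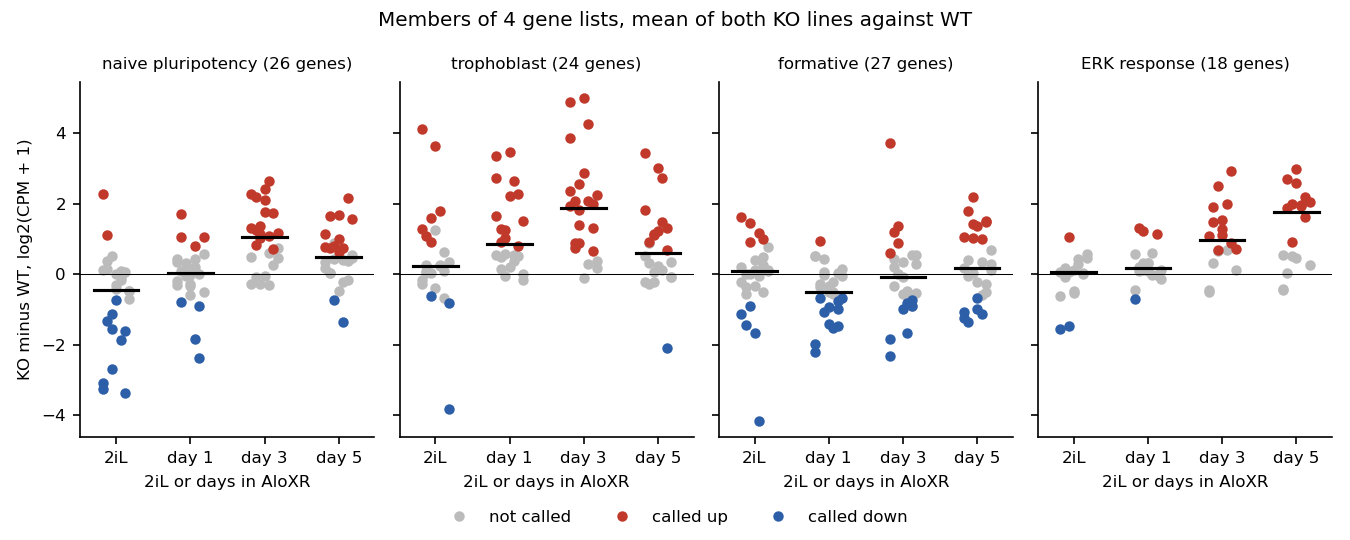
Log2 differences of both depleted lines from WT for each measured member of 4 gene lists (points, genes; red and blue, called higher and lower; black bars, list medians) in 2iL and after 1, 3 and 5 days in AloXR. The naive list has a median of -0.44 in 2iL and 1.05 at day 3, the trophoblast list 1.88 at day 3, the formative list -0.50 at day 1 and the ERK list 1.76 at day 5.

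Neighbouring genes on some chromosomes were shifted together in the depleted lines. On chromosome 14, a segment shared by both lines from 40.9 to 65.3 Mb held 106 genes with at least 10 CPM, whose median against WT was -0.73 in KO2 and -0.92 in KO3 in 2iL, and -0.85 and -1.04 at day 1. The segment holds Otx2, Sall2, Ndrg2, Bmp4, Ero1l, Gata4 and Tdh, among other named genes. Of the genes called lower in both lines, 97 of 1290 in 2iL, 121 of 934 at day 1, 115 of 1101 at day 3 and 107 of 1983 at day 5 lay inside, where 1.26% of tested genes lie. In KO2 the segment ran from 40.9 to 87.5 Mb (median over times -0.79, 95% interval -0.84 to -0.73), and in KO3 from 36.9 to 65.3 Mb (median -0.92, interval -0.97 to -0.88). KO2 was also lower on chromosome 17 from 57.2 to 69.3 Mb (-0.83) and from 74.5 to 94.8 Mb (-0.76), and over chromosome 13 (-0.24). KO3 was higher over chromosome 6 (0.32) and chromosome 8 (0.39), and the end of chromosome 1 was higher in KO2 (0.23) and KO3 (0.35). The start of chromosome 5 was also higher in both, by 0.43 over 17 genes in KO2 (interval 0.31 to 0.79) and by 0.54 over 15 genes in KO3 (interval 0.07 to 0.90). These chromosome 5 segments barely passed the shuffles, with scores of 6.5 against 6.2 in KO2 and 5.8 against 5.8 (rounded) in KO3. Over chromosome 8, the single KO3 libraries lay at 0.22 to 0.50 and those of KO2 at -0.13 to 0.16, with WT at -0.05 to 0.03. Otx2 itself, position-centred, stayed lower in 2iL (-0.82 ± 0.20, adjusted p = 0.00279) and stood at -0.14 ± 0.19 at day 3 (adjusted p = 0.65).

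**Figure D3:**
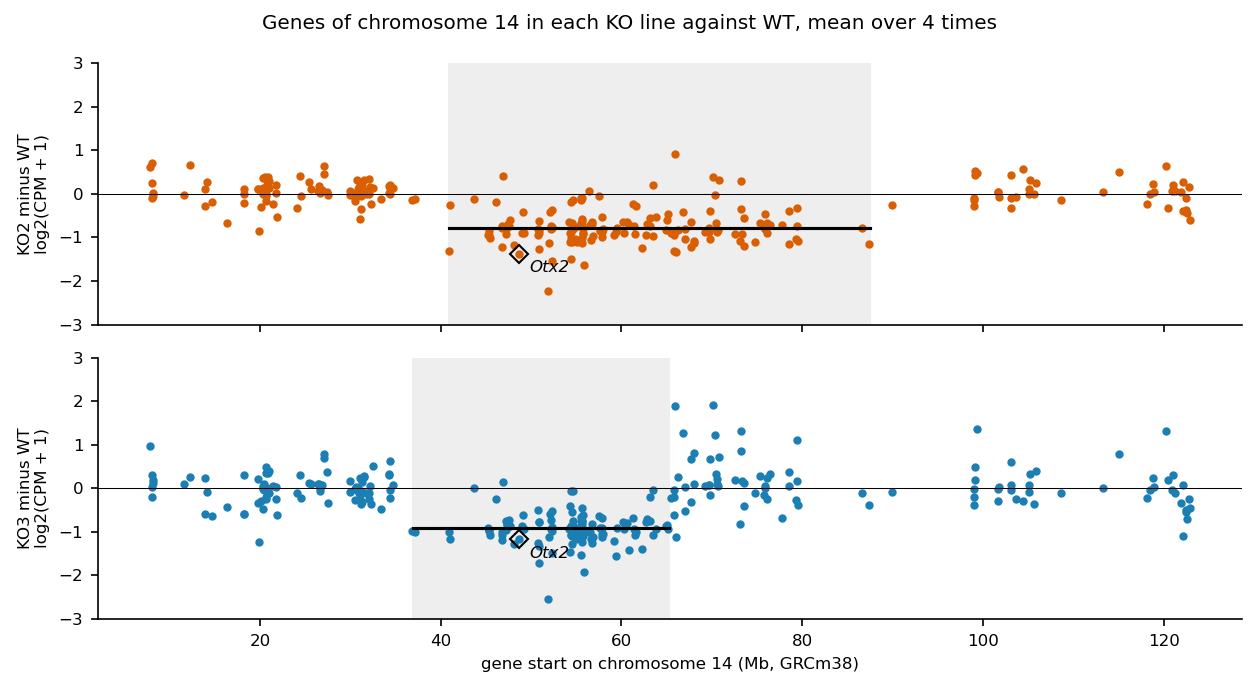
Log2 difference from WT, averaged over 4 times, for each gene of chromosome 14 with at least 10 CPM, against its start in Mb (GRCm38), in KO2 (top) and KO3 (bottom). Grey areas mark the segments from 40.9 to 87.5 Mb in KO2 and from 36.9 to 65.3 Mb in KO3, black lines their medians of -0.79 and -0.92, and the diamond Otx2.

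The WT course describes the passage from naive to formative cells. Naive factors fell between 2iL and day 1 of AloXR, an interval that includes 1 day in N2B27. Tbx3, a T-box factor, fell by 7.56 on the log2 scale, with Tfcp2l1 at -6.36 ± 0.23 (adjusted p = 9.45e-27), Klf2 at -6.13 ± 0.24, Klf4 at -6.12 ± 0.26, Nanog at -4.72 ± 0.18 (adjusted p = 7.43e-25) and Esrrb at -4.55 ± 0.29. Formative genes rose over the same interval. Fgf5 went from 0.25 to 109 CPM (6.48 ± 0.15, adjusted p = 1.35e-34) and Pou3f1 from 4.69 to 387 CPM (6.13 ± 0.19). Dnmt3b, a de novo methyltransferase, went from 68.5 to 2294 CPM (5.22 ± 0.28) and Otx2 from 17.7 to 532 CPM (4.88 ± 0.22). Each of these genes separated 4 of 4 day 1 libraries from the 2iL libraries. Nanog stood at 18.1 CPM at day 1 and at 89.6 CPM at day 5. Genes that rose between 2iL and day 5 include the axonal kinesin Kif1a (6.99 ± 0.20), the smooth muscle actin Acta2 (5.44 ± 0.24) and the keratin Krt18 (4.36 ± 0.24), and Dppa5a fell by 8.28.

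Naive genes fell in WT in 23 of 26 cases and rose in 2 at day 1, and 26 of 26 fell at day 3 and day 5 (the same counts adjusted over the list alone, camera adjusted p = 8.41e-21, 1.42e-31 and 2.79e-35). Formative genes rose in 23, 20 and 18 of 27 cases and fell in 2, 5 and 4 (the same counts adjusted over the list alone, camera adjusted p = 8.51e-20, 5.03e-11 and 4.13e-08). LIF and STAT3 response genes fell, 11 of 14 at day 1 (11 adjusted over the list alone, camera adjusted p = 1.22e-09). Epithelial genes rose in 11 of 18 cases and fell in 1 at day 1 (11 and 1 adjusted over the list alone, camera adjusted p = 1.58e-05, adjusted p = 0.0774 with an estimated correlation). Esrp1, an epithelial splicing factor, was up by 4.46 ± 0.18, and 14 of 18 epithelial genes rose at day 5 (14 adjusted over the list alone, camera adjusted p = 3.66e-09). Wnt response genes fell in 8 of 17 cases and rose in 2 at day 1 (8 and 2 adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.199 with an estimated correlation). Cdx1 (-5.17 ± 0.23) and Sp5 (-4.96 ± 0.35) are 2 of these, in a medium that exchanges a GSK3 inhibitor for a tankyrase inhibitor. Methylation-sensitive germline genes fell in 16 of 20 cases and rose in 2 at day 5 (16 and 3 adjusted over the list alone, camera adjusted p = 1.23e-07). Limma called 6180 genes at day 1 (4016 with a pseudocount of 5 CPM), 7069 at day 3 and 6678 at day 5. In edgeR the median of all genes at day 5 lay lower than in limma (a shift of -0.109), so small changes at that time depend on scaling.

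The course of the depleted lines, their AloXR libraries against their own 2iL libraries, also raised formative and lowered naive transcripts. Pou3f1 rose by 6.67 ± 0.13 at day 1 and 6.92 ± 0.15 at day 5, Fgf5 by 5.84 ± 0.10 and 6.44 ± 0.11, and Otx2 by 5.14 ± 0.15 and 5.12 ± 0.17. The largest falls at day 1 were those of the Wnt target Sp5 (-6.39 ± 0.25), Trpm1 (-6.09 ± 0.24) and Tbx3 (-6.01 ± 0.22), and Esrrb tags fell by 2.86. Naive genes fell in 23 of 26 cases and rose in 1 at day 1, 24 fell at day 3 and 26 at day 5 (the same counts adjusted over the list alone, camera adjusted p = 2.62e-19, 3.08e-25 and 3.33e-27). Formative genes rose in 21, 21 and 23 of 27 cases (the same counts adjusted over the list alone, camera adjusted p = 3.47e-18, 5.80e-15 and 1.26e-13). ERK response genes rose in 12 of 18 cases at day 1 and fell in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 3.15e-04, adjusted p = 0.0902 with an estimated correlation). Two-cell-like genes fell by day 5, 9 of 10 (9 adjusted over the list alone, camera adjusted p = 1.85e-04). Limma called 5479, 6497 and 6672 genes at days 1, 3 and 5, and 3080, 3804 and 3994 with a pseudocount of 5 CPM.

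The difference between the depleted and WT changes from 2iL tests whether the size of the change differed. It also carries any gap between the lines already present in 2iL. At day 1, Klf4 lost less in the depleted lines (2.98 ± 0.32, adjusted p = 3.67e-09), from a lower start in 2iL, and Dnmt3a gained less (-2.47 ± 0.14, adjusted p = 7.31e-18). At day 3, Fgf4 (3.34 ± 0.23, adjusted p = 6.32e-15), Klf4 (4.02 ± 0.33), Nr0b1 (3.62 ± 0.41) and the laminin Lama1 (5.73 ± 0.41) had differences above 0, and Lefty1 (-3.72 ± 0.55) was below 0. At day 5 the differences of Fgf4 (3.77 ± 0.23), Spry2 (3.46 ± 0.32), Lef1 (3.22 ± 0.24) and Dusp6 (3.14 ± 0.30) were above 0, and those of Lefty1 (-5.13 ± 0.55) and Crabp2 (-3.91 ± 0.30) below 0. For genes already at the floor in one of the groups, such as Nr0b1 at day 3, a difference of changes reflects the 2iL levels. Lefty1 and Crabp2 were already higher in the depleted lines in 2iL, which enters their differences below 0. Lama1 at day 3 was not called against WT in KO2 alone. The naive list was lower in 2iL and as a list did not differ from WT at day 1, so its day 1 differences reflect the 2iL gap. Naive genes had differences above 0 in 9 of 26 cases and below 0 in 1 at day 1 (10 and 1 adjusted over the list alone, camera adjusted p = 1.30e-04), and in 17 at day 3 (18 adjusted over the list alone, camera adjusted p = 9.77e-18). At day 5 there were 12 naive genes above 0, with 2 below 0 (13 and 2 adjusted over the list alone, camera adjusted p = 1.80e-09). Trophoblast genes were above 0 in 13 of 24 cases at day 3 (16 up and 1 down adjusted over the list alone, camera adjusted p = 2.33e-09). ERK response genes were above 0 in 11 of 18 cases at day 3 (12 adjusted over the list alone, camera adjusted p = 2.05e-06) and in 9 at day 5 (12 adjusted over the list alone, camera adjusted p = 4.69e-09). Formative genes at day 1 were below 0 in 9 of 27 cases and above 0 in 4 (11 and 4 adjusted over the list alone, camera adjusted p = 6.67e-04, adjusted p = 0.0773 with an estimated correlation). Limma called 1553, 2508 and 3042 genes at days 1, 3 and 5; the day 1 count was 2507 without WT 2iL library 3.

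KO3 and KO2, both depleted for Esrrb by their labels, differed in many genes. Xlr3c, an X-linked lymphocyte-regulated multicopy gene, was lower in KO3 at every time (-3.04 ± 0.33 in 2iL, -4.02 ± 0.29 at day 1, -3.92 ± 0.35 at day 3 and -4.17 ± 0.35 at day 5; at most 4.71 CPM in KO3 against 39.5 to 81.5 in KO2). Esrrb tags were higher in KO3 at day 1 (3.06 ± 0.27, adjusted p = 1.51e-11). The mesoderm factor T was lower in KO3 in 2iL (-3.08 ± 0.40). Later, the endoderm factor Gata6 was higher in KO3, at 8.35 against 0.46 CPM at day 3 (2.71 ± 0.42) and at 14.5 against 0.41 CPM at day 5 (3.47 ± 0.42, adjusted p = 7.43e-08). So were Sox17 (2.97 ± 0.30) and Lama1 (4.08 ± 0.37), which lies in a KO2 chromosome 17 segment of median -0.83. Primitive endoderm genes were higher in KO3 in 15 of 22 cases at day 5 (16 up and 1 down adjusted over the list alone, camera adjusted p = 2.00e-11). Trophoblast genes were higher in 11 of 24 (14 adjusted over the list alone, camera adjusted p = 8.57e-06). Rhox6 stood apart most among them (3.78 ± 0.59). Cholesterol biosynthesis genes were higher in KO3 at day 5, 19 of 22 (19 adjusted over the list alone, camera adjusted p = 1.75e-17). Among them are the sterol methyl oxidase gene Msmo1 (1.85 ± 0.18) on the raised chromosome 8 and the synthase Hmgcs1 (1.67 ± 0.16) on the lowered KO2 chromosome 13. Two-cell-like genes were lower in KO3 in 2iL, 8 of 10 (8 adjusted over the list alone, camera adjusted p = 5.93e-08). Limma called 1228 genes in 2iL, 2542 at day 1, 1304 at day 3 and 2389 at day 5, and 739, 1231, 864 and 1463 with a pseudocount of 5 CPM. The day 1 count exceeded the 2005 genes called for both lines against WT, a comparison that also required both lines to change alike. The 2iL count fell to 118 with only the groups compared in the fit. With KO3 at 2 libraries, 423 and 482 genes were called at day 3 without KO3 library 1 or 2, and 1083 and 1286 at day 5, the remaining library being assumed to vary like the other groups, and 1977 in 2iL without KO3 library 3.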

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

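All tests weighed in this part, those on chromosome segments, on trophoblast genes and on naive genes, were chosen after the results were seen, whereas the comparison of each library with its group and the tests of differences between times or lines were set before.

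Among 101 sets of 4 libraries, 7 held a library far from the other 3, where about 1 set in 20 does so by chance. Each set was 1 gene, the assigned reads or the mitochondrial share in 1 group, and all 7 were genes. The gap to the nearest library, as a share of the whole range, was 0.837 for Pou5f1 in WT library 1 at day 1 (15.4 CPM, the lowest of the others being 12.58 CPM) and 0.874 in KO2 library 4 at day 5 (16.12 CPM against 12.75 to 13.14). It was 0.928 for Tfcp2l1 in KO2 library 4 at day 1 (3.82 CPM against 6.29 to 6.53) and 0.877 for Otx2 in KO3 library 1 at day 1 (191.31 CPM against 175.03 to 176.95). For Pou3f1 in KO3 library 2 at day 1 it was 0.991 (375.76 CPM against 367.82 to 367.89). At day 5 in WT it was 0.869 for Fgf5 in library 4 (69.18 CPM against 94.34 to 98.87) and 0.865 for Dnmt3a in library 2 (193.38 CPM against 222.81 to 227.78).

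Reference genes called with opposite signs against WT in 2iL and at a later time were tested for that change. Changes of sign between 2 AloXR times, as in Nanog (0.80 at day 1 and -1.36 at day 5), were not tested. Klf4 went from -2.68 in 2iL to 1.35 at day 3 (a change of 4.02), Tfcp2l1 from -1.12 to 1.13 (2.25) and Zfp42 from -0.73 to 1.75 (2.48), with 1.00 at day 5 (1.73). Dnmt3a went the other way, from 1.00 in 2iL to -1.47 at day 1 (-2.47) and -0.90 at day 3 (-1.89). Lef1 went from -1.44 in 2iL to 1.79 at day 5 (3.22). Esrrb went from -2.11 to 0.74 at day 3 (2.85), where its tags were at 1.19 to 1.83 CPM in WT. Between the lines, Esrrb at day 1 was 1.11 in KO3 and -1.95 in KO2 against WT (a tested difference of 3.06), and the mesoderm factor T in 2iL was -0.60 in KO3 and 2.48 in KO2 (-3.08).

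Genes of a chromosome 14 segment were lower in both depleted lines at each time, and 53 weaker segment genes had not been used to find it. Of these, 47 were lower on average (88.7%, exact binomial 95% interval 77.0 to 95.7) against 50.2% of genes as weak elsewhere, which argues against separate regulation of single genes. Normalization or library depth is argued against by the other genes of chromosome 14, whose largest absolute median over 2 lines and 4 times was 0.08. A lower gene dose of the segment may account for it: the 53 weaker segment genes had a median of -0.56. For Otx2, segment dose alone is argued against in 2iL, where the position-centred value was -0.82, and could account for its difference at day 3, where it was -0.14. Whether the segment is lost from 1 chromosome copy was not tested, since DNA was not measured here.

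Trophoblast genes were higher in both depleted lines at day 3. A shift shared with neighbouring genes does not account for the list, since 19 members were still called higher after it was subtracted. Raised segments had medians of at most 0.54 (log2), so the subtraction could remove little. Effects of segment genes on genes elsewhere were not tested. The rise was not confined to 1 line, since 17 members in KO2 and 19 in KO3 were at least 1.5-fold higher. Both lines share shifted segments, however, so their agreement may not be that of independent lines. Cells of trophoblast type in the cultures cannot be told apart from a rise within the cells: Cdx2 reached 1.31 CPM, too near the floor to exclude them, while Krt18 (369.63 CPM in KO2) and Peg10 (330.02 CPM in KO3) were the most abundant members. Gata3 (4.88 and 8.77 CPM against 0.48 in WT) and Elf5 (0.16 and 0.21 CPM), chosen after their values were seen, were higher or near 0, and Eomes was lower (15.13 and 17.42 CPM against 27.67). Of the 24 members, 7 are also in other lists, and a direct effect of Esrrb loss stays open as an untested biological explanation.

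Naive genes were higher in both depleted lines at day 3, 16 of them. Cells left in the full 2iL state of their own line are argued against for Dppa2, Fgf4, Klf5 and Stat3. These 4 members need more such cells than the 1.2% in KO2 and 2.51% in KO3 that the level of Klf2 allows. In KO2 the margin for Dppa2 is narrow, with at least 1.37% needed. These limits use 2 SD of the day 3 libraries and leave out the spread of the 2iL and WT levels. In KO3, where that SD comes from 2 libraries, 5 further members also had limits above what Klf2 allows. They need at least 69.01% (Dppa4), 12.18% (Dppa5a), 11.33% (Klf4), 5.86% (Fbxo15) and 2.89% (Zfp42). For Zfp42 the margin over 2.51% is too narrow to decide. The others argue against such cells only as far as 2 libraries can. Such cells cannot be told apart from a change within the cells for the other 7 members in KO3 and for 12 members in KO2, since their levels need no larger share there. Cells left in a partly naive state, with lower levels than in 2iL, were not tested for any member. A return of naive transcripts after day 1 is argued against for the list as a whole, since 0 of the 16 members had a higher mean at day 3 than at day 1 in both lines. In single lines, Klf4 was higher by 0.59 in KO3, Klf2 by 0.04 in KO3 and Tbx3 by 0.09 in KO2, so a return of Klf4 in KO3 stays open. Of the 26 members, 10 are also in other lists.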

How the results depend on the processing

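The position-centred fit, the fit without 2iL library 3 of each line, the replicate block and the leave-one-out fits of Esrrb were chosen after the results were seen, the others before. Of 467 alternative values of the main results, 414 were counted as the same and 53 moved. A count of called genes was the same if its total lay within 1.5 times, whatever the balance of higher and lower genes. At day 5, KO against WT went from 1508 higher and 1983 lower to 1720 and 1665 with median-of-ratios scaling. That count was still the same by this rule. Where a stricter or looser fold minimum moved a count its construction is the reason, and elsewhere the cause was not tested. With a 2-fold minimum limma called 1157, 649, 1052 and 1182 genes (KO against WT in 2iL and at days 1, 3 and 5), 3374, 4254 and 4105 (WT course), 2503, 3286 and 3525 (KO course), 998, 1668 and 1810 (KO minus WT change), and 623, 816, 641 and 1123 (KO3 against KO2). With no fold minimum it called 3372 and 5333 (KO against WT, days 1 and 5), 8916 (KO course, day 1) and 3931 (KO3 against KO2, day 1). With a pseudocount of 5 CPM, which shrinks weak genes, the counts were 1396, 848, 1338 and 1731 (KO against WT), 4016 (WT course, day 1), 3080, 3804 and 3994 (KO course), and 739, 1231, 864 and 1463 (KO3 against KO2). With only the groups compared in the fit, 1385 (KO against WT) and 118 (KO3 against KO2) genes were called in 2iL, and position-centred 826 (KO3 against KO2, day 3). With an estimated correlation between genes, camera passed 4, 6, 12 and 8 lists (KO against WT), 6 and 9 (WT course, days 1 and 5) and 2, 6 and 5 (KO minus WT change), and fry passed 23 and 22 (WT course, days 3 and 5). Leaving out each library in turn gave 423 (without KO3 library 1; 482 without library 2) to 1369 genes for KO3 against KO2 at day 3, 1083 (without KO3 library 1; 1286 without library 2) to 2304 at day 5, 878 to 1977 (without KO3 library 3) in 2iL, and 1092 to 2507 (without WT 2iL library 3) for the KO minus WT change at day 1. The other 13 comparisons stayed within 1.5 times, KO against WT in 2iL for instance at 2155 to 3352. Named genes that reversed were Usp17la (0.14 in edgeR, KO minus WT change at day 1), Gsc (-0.08 in edgeR, day 5), Gata6 with KO2 alone (-1.16 and -1.20, KO course at days 3 and 5) and Esrrb with KO3 alone (1.11, KO against WT at day 1). Named genes kept 96.4% of their calls with a pseudocount of 0.25 CPM, 89.2% with 5 CPM, 81.4% with a 2-fold minimum, 96% with no filter, 94.5% over the fits without 1 library, 91.1% with only the groups compared, 98.1% with median-of-ratios scaling, 96.9% with quantile normalization, 93.8% in edgeR, 83.7% with KO2 alone, 88.9% with KO3 alone, 87.7% when position-centred and 95.4% with the replicate block. The share of called genes that were higher moved from 62.4% to 50.7% with quantile normalization (KO against WT, day 3), and from 34.5% to 46.1% in 2iL, 72.5% to 55.8% at day 3 and 64.1% to 51.3% at day 5 for KO3 against KO2. Depth limits genes under about 3 reads per library, such as Esrrb at day 5.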

Other observations

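In this part, the tests of splits of the libraries, the replicate block and the fit without 2iL library 3 were chosen after the results were seen, whereas the gene tests in the next paragraph were set before.

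Gbp2, Gbp2b and Ifitm7 were higher in the depleted lines at day 1 of AloXR. No list of interferon-inducible genes was tested. Gbp2, a guanylate-binding protein gene (ENSMUSG00000028270, chromosome 3), stood at 1.81 CPM in WT, 38.6 in KO2 and 13.4 in KO3 at day 1 (3.19 ± 0.26, adjusted p = 2.53e-13, 8 of 8 libraries) and rose by 3.94 ± 0.28 at day 3 (6 of 6 libraries). Its neighbour Gbp2b (3.06 ± 0.23) and the interferon-induced transmembrane gene Ifitm7 (3.24 ± 0.23) rose at day 1, each in 8 of 8 libraries. All 3 belong to families whose copies can share reads. At day 5, the largest rise among genes of at least 5 CPM was that of Psors1c2, from 1.72 CPM in WT to 51.9 in KO2 and 20.8 in KO3 (3.62 ± 0.26, adjusted p = 1.76e-14), followed by Peg10, the kinase gene Sgk1 (3.29 ± 0.36) and the hormone precursor gene Trh (3.15 ± 0.39), each in 6 of 6 libraries.

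Between the 2 depleted lines, 2 further multicopy genes stood apart, each at the time given. Nlrp4c, a gene of oocytes and early embryos, was lower in KO3 than in KO2 at day 1, at 3.43 against 43.1 CPM (-3.44 ± 0.27, adjusted p = 1.35e-12). Xlr4b, X-linked like Xlr3c, was lower in KO3 at day 5, at 1.86 against 23.4 CPM (-3.08 ± 0.28, adjusted p = 3.35e-11). WT held 4.81 CPM of Xlr4b at day 5, between the 2 lines.

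In 2iL, library 3 of each line held more Dnmt3b than the other 2, at 120.6 CPM in WT, 107.3 in KO2 and 115.9 in KO3 against 39.7 to 59.9 CPM in the others. Deviations from the group mean were correlated between lines across 8495 genes. The values were 0.30 to 0.57 for libraries numbered 1 and 0.05 (WT and KO2) to 0.19 for those numbered 2. For those numbered 3 they were 0.52 to 0.67, so these deviated together. Deviations within a line cancel out over its libraries, so the correlations of numbers 1 and 2 may follow in part from those of number 3. The numbers follow the order of accession and the labels give no pairing. With the number as a block within each time, limma called 2494, 2219, 3102 and 3811 genes for the depleted lines against WT in 2iL and at days 1, 3 and 5, and 1015, 2905, 1448 and 2599 for KO3 against KO2.

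Other splits of the same libraries were drawn for each comparison with at least 3 libraries per group. They test chance over libraries, and cannot tell the effect of Esrrb loss from other differences between 1 WT line and 2 depleted lines. Each count of splits below includes the real one. For the depleted lines against WT in 2iL, 1 of 84 splits, the real one, gave as many as 2666 genes, which argues against chance over libraries. The highest other split gave 2564 and set WT libraries 1 and 2 with KO3 library 1 against the rest, where the other splits had a median of 262. That points to a structure of the samples in 2iL that crosses the lines. At day 1, 1 of 100 splits drawn from 495, the real one, reached 2005. This argues against chance over libraries, though splits that were not drawn could reach it too. The highest other (1895) set all 4 KO2 libraries against WT and KO3, so a split between lines gave nearly as many. In the WT course, 1 of 35 splits reached the real count at day 1 (6180, highest other 4100) and day 3 (7069, highest other 5104). The same held at day 5 (6678, highest other 4769). These counts argue against chance over libraries, and the highest other split had 1 library out of place each time. In the KO course at day 1, 1 of 100 splits drawn from 1225 reached 5479 (highest other 3077), which argues against chance over libraries. For the KO minus WT change at day 1, 3 of 100 splits drawn from 41580 reached the real 1553, the real one included. That share is under 0.05, but only 100 splits were drawn and another gave more genes than the real one, so chance is not excluded here. The highest other gave 2117, more than the real split, with WT 2iL libraries 1 and 2 and KO3 2iL library 1 together again, so the structure of the 2iL samples bears on this count. For KO3 against KO2, 1 of 35 splits at day 1 reached 2542 (highest other 28), which argues against chance over libraries. In 2iL the 10 splits are too few for this test. There 2 of them reached the real 1228, the highest other with 1736 genes, setting KO2 library 1 and KO3 libraries 1 and 2 apart.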
